A study of Oryza sativa with 18 samples.

How the data were processed

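The series holds ATAC-seq data, in which a transposase inserts sequencing adapters into DNA that is not wrapped in nucleosomes, so that reads pile up where chromatin is accessible. Per the labels' protocols, nuclei were isolated from frozen, ground leaves of rice (Oryza sativa, variety Azucena), and the libraries were read from both ends on a HiSeq, 9 to a lane. Which library was on which lane is not given in the sources used here. There are 18 libraries in 9 groups of 2, which cover 5 treatments. Plants in hydroponic culture were kept at 30 °C as controls, moved to 40 °C, returned from heat to 30 °C, taken out of the liquid so that the roots met air, or returned to liquid after such exposure.

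A single list of open regions for the whole series was analysed. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.3. The genome build, the read filters, the region caller and the way the 18 libraries were combined are not given in the sources used here. Each row of the deposited list has a sequence name, a start, an end and an attribute string with a region identifier and the attributes max and maxpos. In each of the 29978 rows the start and the width written into the identifier equal the start and the width from the coordinates. The attribute max, called the peak value below, holds whole numbers from 10 to 18 and is not defined in the file or the labels. The attribute maxpos lies between 1 and the width of its region in every row and was read as the position of the peak in bp, counted from the lowest coordinate. All values are used as the authors deposited them, with no scaling.

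The list names no library, treatment or time point, and 0 columns of per-sample values exist in it to be left unused. The read depth per library is therefore unknown, no spread between replicates can be computed, and the planned comparisons between heat, dehydration, recovery and control could not be made. No genome sequence came with the file. The gene table at hand belongs to an assembly whose match to the file's coordinates could not be established, so no gene, motif, GC content or distance to a transcription start is reported, and the fixed gene lists and the rule for named genes could not be applied. The part of that rule that could be kept is the naming of the 5 widest chromosomal regions, which are given by position. Coordinates are 1-based and are those of the deposited file.

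Statistics were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The main values rest on chromosomes 1 to 12, and the sequences named ChrC, ChrM, ChrSy and ChrUn are described apart. Chromosome lengths are not in the file, so the end of the last region stands for the length of a chromosome, which it can only understate. Errors are standard deviations over the 12 chromosomes or over bins of 1 Mb. These are parts of 1 pooled list and not biological replicates, and their spread says nothing about the variation between plants. Only bins lying wholly before the last region were used.

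Spacing was compared with 1000 random placements of the same widths on the same chromosome, without overlap and with at least 72 bp between regions, the smallest gap in the file. For the altered lists named below, the smallest gap of each list was kept instead. A second set of 1000 placements kept the number of regions in each 1 Mb bin. P-values are two-sided, and the smallest that 1000 placements can give is 0.002. Differences in density between chromosomes were tested by permuting the bins among chromosomes 100000 times, and between the lower-coordinate and higher-coordinate sides of a chromosome by permuting its bins 20000 times with Benjamini-Hochberg adjustment over the 12 chromosomes. Quantities computed once per chromosome were tested with an exact two-sided sign-flip permutation test over the 12 chromosomes, whose smallest possible p is 0.000488. The number and width of the regions and the relation of width to peak value were to be described from the start. The tests of spacing and of density, the description of peak position, and the sign-flip test of width against peak value, were chosen after the file had been seen, as were the bins, gaps and groups named by position.

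The tests were tried on simulated lists, of which the uniform ones held 29831 regions each. Over 40 uniformly placed lists the ratio of short gaps to random placement averaged 1.00, and 2 lists passed the spacing threshold of 0.05. These lists were drawn by the same placement procedure as the test uses, so this checks the computation alone. Uniform lists also have no sparse or dense stretches along a chromosome. They therefore do not show how the permutations of bins behave where neighbouring bins resemble each other. A list seeded with 1.5 times the density in the outer 25% at each end, made by dropping inner regions from a uniform list, gave back a ratio of 1.48. The alternatives tried were merging regions less than 150 bp apart, keeping regions of at least 100 bp, keeping the upper part of the list by peak value, other bins and distances, placement within bins, each end of the chromosomes on its own, leaving out each chromosome in turn, and leaving out the 2 chromosomes farthest from the median length.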

Results

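Accessible chromatin was mapped by ATAC-seq in the second leaf of 14-day-old rice plants of the variety Azucena. The 18 libraries fell into 9 groups of 2. Control plants at 30 °C were sampled at 0.5 h, 2 h and 4 h, and plants moved to 40 °C at the same 3 times. Heat recovery was sampled 2 h after plants that had spent 2 h at 40 °C were put back at 30 °C. Dehydrated plants were sampled after 2 h with their roots in air, and dehydration recovery 2 h after the return to liquid of plants that had spent 1.5 h in air. The design asks which chromatin opens or closes under heat and water loss and whether it returns. The processed data analysed here are a single list of 29978 open regions for the whole series, with no value per library, so no treatment was compared with another and the depth per library is unknown.

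The listed regions were short and covered a small part of the genome. On chromosomes 1 to 12 there were 29831 regions, which summed to 7.83 Mb, or 2.10% of the 372.8 Mb up to the last region of each chromosome. The median width was 206 bp, with quartiles of 111 and 337 bp, and 343 regions (1.15%) were wider than 1000 bp. No region was narrower than 72 bp, and 1946 chromosomal regions were exactly that wide against 277 that were 1 bp wider. Regions under 150 bp made up 35.5% of the chromosomal list. The median width varied little between chromosomes, at 205 bp ± 5.90 (SD, n = 12 chromosomes).

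The 5 widest chromosomal regions all had the highest peak value, 18. The widest spanned 4797 bp on chromosome 1, from 1737259 to 1742055. The next were 4139 bp on chromosome 4, from 32883685 to 32887823, and 4138 bp on chromosome 1, from 25701512 to 25705649. They were followed by 2910 bp on chromosome 5, from 18105611 to 18108520, and 2885 bp on chromosome 12, from 20541409 to 20544293. Which genes lie there was not analysed here.

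Wide regions had high peak values. The peak value is a whole number that the file gives for each region without a definition, and it ran from 10 to 18. Chromosomal regions at 12 had a median width of 79 bp, those at 15 of 189 bp and those at 18 of 432 bp. Within chromosomes, width and peak value correlated across regions with a mean Spearman rho of 0.80 ± 0.015 (SD, n = 12 chromosomes), positive in all 12 (exact sign-flip permutation test, p = 0.000488, the smallest it can give). Regions are not independent replicates, so this describes the list. If the peak value is the highest value over the bases of a region, it can only stay or rise as bases are added. Width and peak value would then go together on every chromosome in advance, so nothing is concluded from this p.

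Peak values piled up at their upper end. The classes from 13 to 17 held between 3875 and 4299 chromosomal regions each, while the class at 18 held 6645, or 22.3%. The classes at 10, 11 and 12 held 13, 459 and 2385 regions. The share at 18 was 22.7% ± 1.99 over the chromosomes (SD, n = 12) and ranged from 19.2% on chromosome 4 to 26.5% on chromosome 12. Regions next to each other shared almost no peak value, with a Spearman rho of 0.016 over 29819 neighbouring pairs, against 0.0014 ± 0.0058 (SD) when values were permuted within chromosomes (permutation test, two-sided p = 0.00799).

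**Figure D1:**
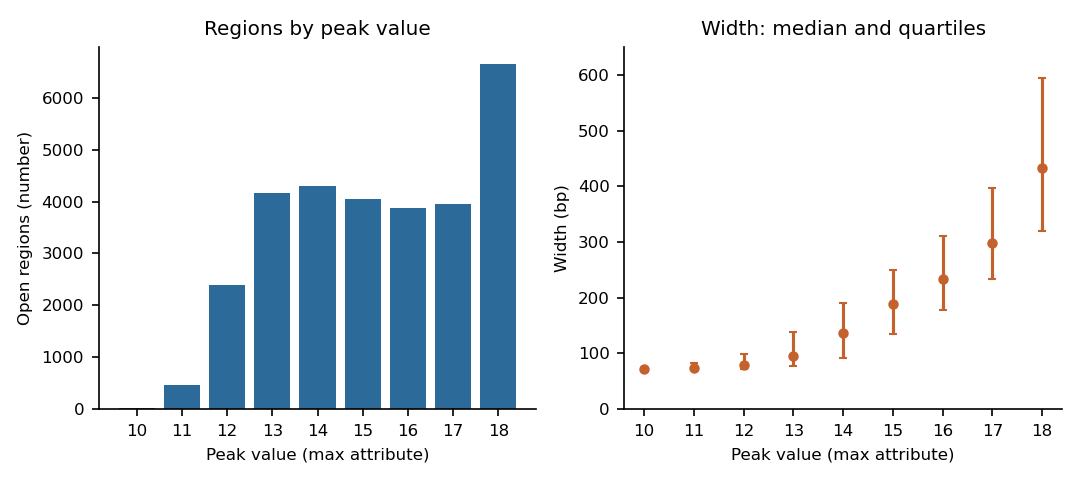
Left, number of chromosomal open regions (vertical axis) at each peak value (horizontal axis). Right, width in bp at each peak value, with points for the median and bars for the quartiles. The class at 18 is the most frequent, with 6645 regions, and the median width goes from 72 bp at a peak value of 10 to 432 bp at 18.

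The peak position lay more often on the lower-coordinate side of a region than on the other. This was so for 74.0% ± 1.19 of the regions (SD, n = 12 chromosomes). By peak value, the share fell from 100% at 10 and 92.8% at 11 to its lowest, 67.1%, at 16 and was higher again at 18, at 80%. The median peak position was 1 bp from the lowest coordinate at a peak value of 10, 10 bp at 11 and 128 bp at 18, where the median widths were 72, 73 and 432 bp. How the file reports a peak that is tied over several positions is not stated, and the share under no preference is therefore unknown, so no test was made. The 100% and the median position of 1 bp at a peak value of 10 are what reporting a tie at its first base would give. The 74.0% therefore cannot be read as a trait of the regions.

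Open regions were unevenly spread between chromosomes. Chromosome 3 had the most regions per Mb, 100.96, followed by chromosome 1 with 97.8 and chromosome 2 with 94.8. Chromosome 11 had the fewest, 53.7, and chromosome 12 had 60.1. The mean over the chromosomes was 78.3 regions per Mb ± 15.4 (SD, n = 12). Differences between chromosomes made up 20.8% of the variance of the 366 bins of 1 Mb (permutation of bins, p = 1e-05, the smallest that 100000 permutations can give). Neighbouring bins resembled each other, with a correlation of 0.52 over 354 pairs, so this p is too small. With blocks of 5 Mb the share was 38.0% and p was 0.0025. Permuted bins give a larger share when bins are fewer, so the 38.0% does not mean a stronger difference than the 20.8%.

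Longer chromosomes held more regions, and over the 12 chromosomes more per Mb as well. The number of regions correlated with the position of the last region at Pearson's r = 0.90 (permutation p = 9e-05, adjusted 0.00018) and Spearman's rho = 0.90 (permutation p = 0.00022) over the 12 chromosomes. Regions per Mb correlated with it at r = 0.64 (permutation p = 0.023, adjusted 0.023) and rho = 0.71 (permutation p = 0.0127). Without chromosomes 1 and 9, which lie farthest from the median length, r was 0.83 for the number (permutation p = 0.003, n = 10) and 0.58 for the density (permutation p = 0.0808, n = 10), which no longer passed the threshold. An even spread of regions would also make their number rise with length, so only the relation of density to length bears on how they are distributed. The relations of number and of density were 2 tested together, and no batch could be examined in a pooled list.

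Along chromosomes 4, 9 and 10 the lower-coordinate part was poor in open regions. The short arms of chromosomes 4 and 10 are known from cytology to be rich in heterochromatin, the compact and mostly silent form of chromatin. The file marks no arms or centromeres, so whether the sparse parts match those arms was not tested. On chromosome 4 the first 17 bins held 33.8 regions each ± 16.2 and the last 17 held 100.9 ± 21.4 (SD between bins), a ratio of 0.34 (permutation of bins, adjusted p = 0.0003). The ratio was 0.43 on chromosome 9 (permutation, adjusted p = 0.0003) and 0.47 on chromosome 10 (adjusted p = 0.0014). Chromosomes 7 and 5 also passed the threshold, with ratios of 0.71 (permutation, adjusted p = 0.0159) and 0.72 (adjusted p = 0.0478). With the upper part of the list by peak value alone, 3 chromosomes passed, and these were 4, 9 and 10. The other 7 chromosomes did not pass, and their ratios lay between 0.84 and 1.27. Because neighbouring bins are correlated, these p-values are too small as well.

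The change on chromosome 4 was abrupt. The 19 bins below 19 Mb held 11 to 62 regions each, and the 16 bins above it held 76 to 134. The boundary was chosen after the values were seen, so no test was made.

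**Figure D2:**
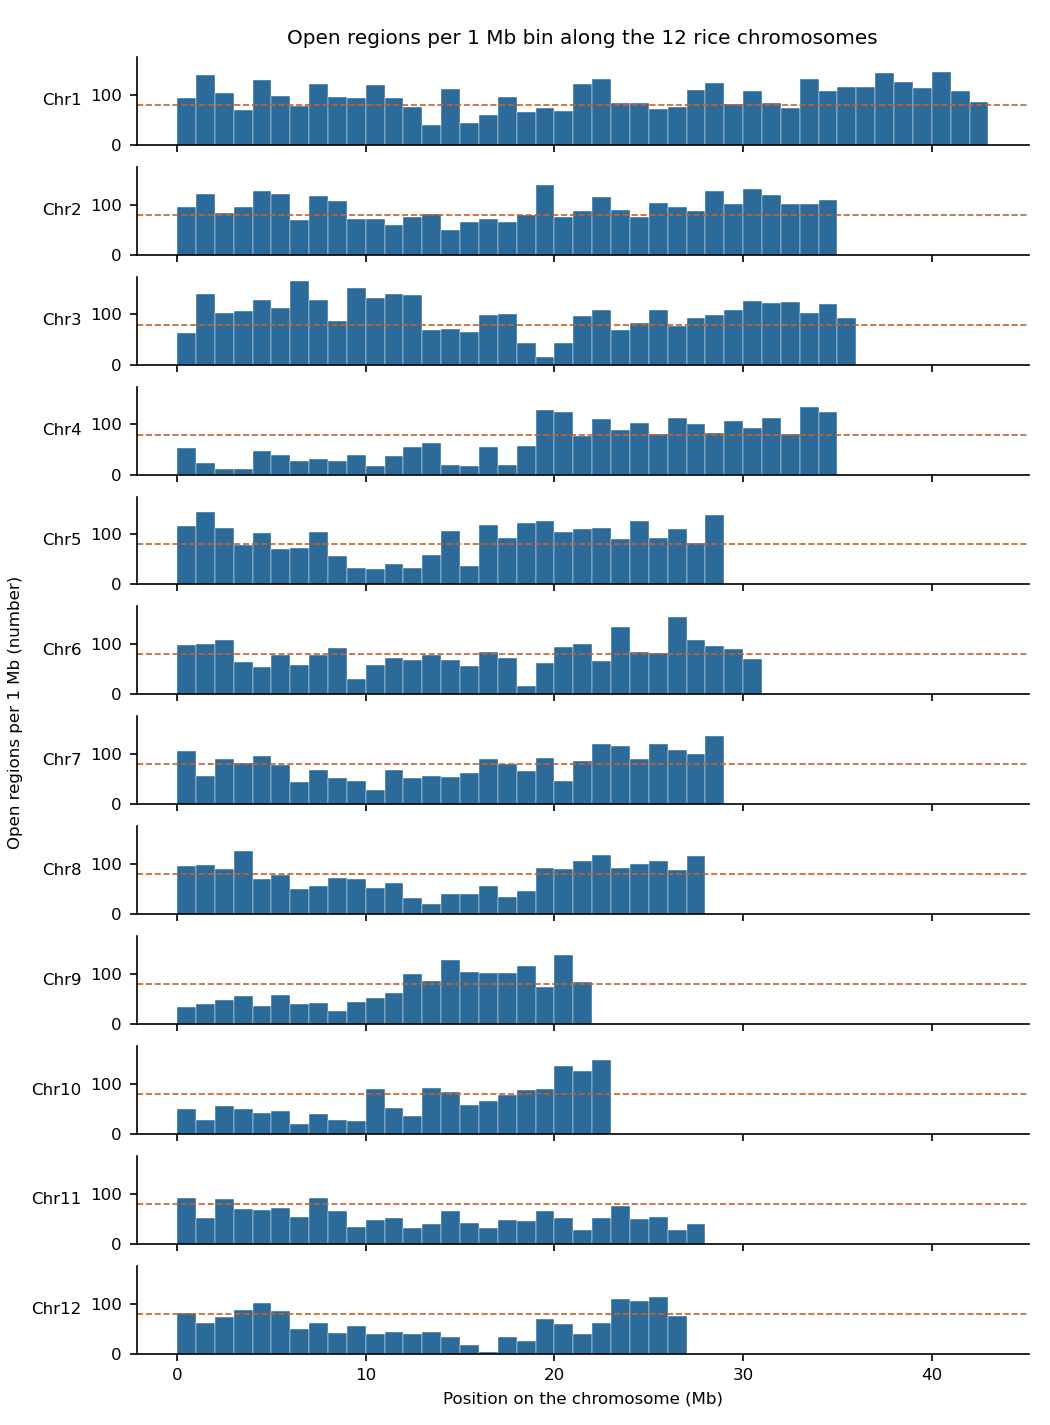
Number of open regions per 1 Mb bin (vertical axis) against position in Mb (horizontal axis) for chromosomes 1 to 12; the dashed line is the mean over all 366 bins, 79.7. Bins on chromosome 4 stay at or below 62 regions up to 19 Mb and at or above 76 beyond it, and chromosome 11 has the lowest density, 53.7 per Mb.

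Open regions were denser in the outer parts of chromosomes than in their middle when both ends were pooled, and of the ends on their own the higher-coordinate one alone passed the test. The outer 25% of the length at each end held 1.34 times as many regions per Mb as the part between them (mean log2 ratio 0.43 ± 0.27, SD, n = 12 chromosomes), with a ratio above 1 on 12 of 12 chromosomes (exact sign-flip permutation test, p = 0.000488). The ratio was 1.96 on chromosome 12, 1.62 on chromosome 8 and 1.53 on chromosome 7. It was 1.04 on chromosome 4 and 1.00 on chromosome 9. Taken alone, the higher-coordinate end held 1.51 times the density of the middle (mean log2 ratio 0.59 ± 0.34, SD, n = 12; exact sign-flip p = 0.000977), with a ratio above 1 on 11 of 12 chromosomes and 0.93 on chromosome 11. The lower-coordinate end did not pass the test, at 1.11 times (mean log2 ratio 0.16 ± 0.56, SD, n = 12; exact sign-flip p = 0.353). It was sparser than the middle on chromosomes 4, 9 and 10, with ratios of 0.46, 0.62 and 0.87. The ends were taken apart after the pooled ratio had been seen.

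Single bins ranged from 4 to 166 open regions around a mean of 79.7 ± 32.9 (SD, n = 366 bins). The emptiest bin was the one from 16000001 to 17000000 on chromosome 12, with 4 regions. The bins from 2000001 to 3000000 and from 3000001 to 4000000 on chromosome 4 held 12 and 11, and the bin from 19000001 to 20000000 on chromosome 3 held 16. The fullest bin, with 166 regions, ran from 6000001 to 7000000 on chromosome 3. A bin from 26000001 to 27000000 on chromosome 6 followed with 154.

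Long stretches held no open region at all. The longest was 722.6 kb on chromosome 12, from 5822531 to 6545147, followed by 544.5 kb on chromosome 4, from 1230179 to 1774698, and 430.9 kb on chromosome 7, from 11894774 to 12325698. The longest stretch of each chromosome averaged 375.2 kb ± 145.8 (SD, n = 12). Each was longer than the longest in any of 1000 random placements on that chromosome, by a factor of 2.37 (chromosome 1) to 5.56 (chromosome 12) over the random mean. The placements treated all sequence as able to hold a region. Sequence that cannot be aligned uniquely would leave such stretches too, which was not tested.

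Neighbouring open regions were often close together. Of 29819 gaps between neighbours, 8239 (27.6%) were under 1000 bp, against 7.60% ± 0.146 in random placements (SD over 1000 placements), a ratio of 3.64 (random placement test, n = 29819 gaps, two-sided p = 0.002, the smallest it can give). Keeping the number of regions in each 1 Mb bin raised the random share to 8.48% ± 0.151, and the ratio was then 3.26 (n = 29819 gaps, p = 0.002, again the smallest). The share was 27.3% ± 1.56 over the chromosomes (SD, n = 12), lowest on chromosome 11 at 24.1% and highest on chromosome 1 at 30.1%. Among gaps under 2000 bp the excess fell with distance. Gaps of 72 to 150 bp were 9.06 times as frequent as in the placements within bins, gaps of 500 to 1000 bp 1.86 times and gaps of 1000 to 2000 bp 1.13 times. Gaps of 8000 to 16000 bp were fewer than in those placements, at 0.64 times. Beyond that the ratio rose again, to 1.07 for gaps of 32000 to 64000 bp and 2.15 for gaps of 64000 bp or more, of which there were 881 against a mean of 409 and a highest value of 456 in 200 placements.

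Regions less than 1000 bp apart formed 5297 groups of at least 2, and 16295 regions (54.6%) had no neighbour that close. There were 297 groups of 5 or more, against a mean of 2.32 and a highest value of 7 in 200 placements within bins. The largest group held 13 regions within 6467 bp of chromosome 4, from 20493639 to 20500105. Groups of 12 lay on chromosome 1, from 11606656 to 11614148, and on chromosome 2, from 19594380 to 19601137. The largest group in the 200 placements within bins held 9.

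**Figure D3:**
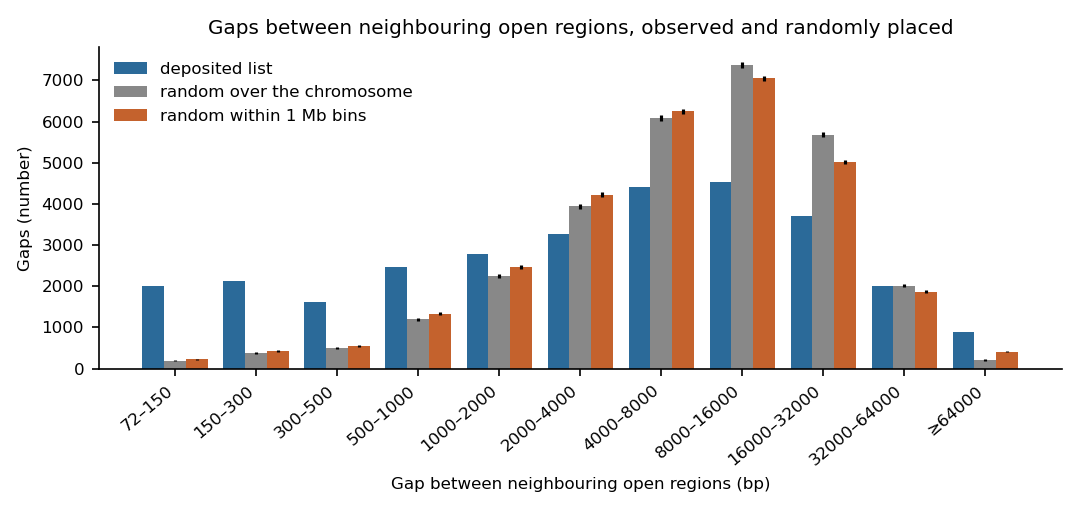
Number of gaps between neighbouring open regions (vertical axis) by gap length in bp (horizontal axis) in the deposited list and as the mean of 200 random placements over the chromosome or within 1 Mb bins, with bars for the SD over placements. The deposited list has 2015 gaps of 72 to 150 bp against 222 within bins, and fewer gaps than both sets of placements from 2000 to 32000 bp.

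Bins with many regions did not differ detectably from bins with few in the mean peak value of their regions. The Spearman rho between the number of regions per bin and their mean peak value was -0.16 ± 0.27 (SD, n = 12 chromosomes), negative on 8 of 12 (exact sign-flip permutation test, p = 0.0703). With bins of 500 kb it was -0.10 and p was 0.021, and without chromosome 10 it was -0.19 and p was 0.0283, so the call rests on such choices.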

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

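The tests in this part were chosen after the values were seen.

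Regions outside the 12 chromosomes were set apart because the comparisons above do not use them. There were 41 on ChrC and 73 on ChrM, which are taken from their names to be the chloroplast and mitochondrial sequences, 26 on ChrSy and 7 on ChrUn. The organelle regions were 0.38% of the list but 2.22% of its base pairs. Of these 114 regions, 92 (80.7%) had a peak value of 18, against 6645 of 29831 (22.3%) on the chromosomes (Fisher's exact test, two-sided, p = 1.18e-39, with regions as units, which are not independent). ChrM held 4 regions over 10000 bp, which made up 63.0% of its open base pairs, and chromosomes 1 to 12 held 0. The longest ran over 30657 bp from 225389 to 256045, and the next over 22973 bp from 386885 to 409857.

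Organelle DNA carries no nucleosomes, so it could have been open and callable throughout. The list argues against this as the whole account, because regions covered 24.6% of ChrC and 40.1% of ChrM between their first and last regions. The high number of organelle genomes per cell may be what brings 80.7% of these regions to the highest peak value, but absence of nucleosomes predicts the same, and the list cannot tell them apart. Width differed too, since 27.2% of organelle regions were wider than 1000 bp against 1.15% of chromosomal ones, with medians of 232 and 206 bp. Wide regions had high peak values on the chromosomes, and the shares at 18 were not compared at matched width. The longest gap on ChrC was 23810 bp, from 78907 to 102716, and no region lay beyond 114100. The longest gap on ChrM was 47877 bp, from 339008 to 386884. A candidate explanation is that sequence present more than once, such as the inverted repeat of the chloroplast genome, received no regions. This stays open because it needs the genome sequence, and whether that repeat bears on the gap on ChrM was not tested. No biological difference named by the design was tested.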

How the results depend on the processing

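All alternatives other than those for the number and width of regions were chosen after seeing the data, as were the tests of spacing and density themselves. The number of regions was 27944 after merging regions less than 150 bp apart, 23481 for regions of at least 100 bp, and 14595 for the upper part by peak value, where the cause is the smaller list. The median width was then 222, 253 and 330 bp. The excess of short gaps kept its direction and passed the threshold under every alternative run. So did the relation of width to peak value, which may be fixed in advance, as said above. The differences between chromosomes passed under every alternative as well, but a share of variance has no direction to keep. The ratio of short gaps to random placement lay between 1.54 (gaps under 5000 bp) and 5.40 (under 500 bp), and the mean rho of width and peak value fell from 0.80 to 0.51 in the upper part by peak value, which spans fewer values. The outer to inner ratio lay between 1.29 and 1.38 with both ends and passed, was 1.51 with the higher-coordinate end alone (exact sign-flip p = 0.000977) and did not pass with the lower-coordinate end alone (1.11, p = 0.353), which is sparse on chromosomes 4, 9 and 10. Without chromosomes 1 and 9 the relation of regions per Mb to chromosome length did not pass (r = 0.578, p = 0.0808), and that of the number of regions did (0.827, p = 0.003). The number of chromosomes whose sides differed was 5 and became 6 after merging and 3 in the upper part by peak value. The relation of density to peak value passed the threshold after merging (rho -0.158, p = 0.0483), with 500 kb bins (-0.102, p = 0.021), without chromosome 5 (-0.186, p = 0.0449) and without chromosome 10 (-0.195, p = 0.0283). In its other 14 alternatives it did not pass, and the cause was not tested. No result reversed. No paired analysis was possible because the list holds no values per library, and for the same reason no replicate could be left out and no other count model could be run. The settings fixed beforehand for gene features, distance to transcription starts, promoters, gene lists, motifs and GC content were not run, since they need a genome or annotation of the file's build. Depth per library is unknown, so it cannot be said how many open regions were missed.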

Other observations

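The tests in this part were chosen after the values were seen.

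The meaning of the peak value decides what the list can say about stress. No peak value exceeded 18, which is also the number of libraries, and 6645 chromosomal regions sat at that limit. Organelle reads are usually the most abundant in such libraries, so a read depth would be predicted to go higher there, yet the highest organelle value was also 18, which argues against a depth and is consistent with a count of libraries in which a base was open. A depth capped at 18 stays open, since the file defines neither attribute.

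If the peak value does count libraries, the list may hold no chromatin that is open in the heat-exposed libraries alone or in the dehydrated ones alone. The lowest value was 10, while of the 18 libraries 8 were exposed to heat, recovery included, and 4 to dehydration, so a region open in the heat-exposed libraries alone would have a value of at most 8, and 0 regions had one. From a value of 13 at least 1 of the 6 control libraries would be needed, and 27119 regions (90.5%) had such a value. The other 2859 regions, at 10 to 12, would need none, so they could be open in the 12 stressed libraries and closed in the controls, which the list cannot show. The 13 chromosomal regions at 10 had a median width of 72 bp, the smallest in the list, and a median peak position of 1 bp. A cutoff at 10 in making the list would leave regions of this kind. The 0 regions at or below 8 therefore cannot be read as an absence of such chromatin. How the libraries were combined is not given in the sources used here, so a cutoff could not be checked.

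The closeness of neighbouring regions has at least 2 technical readings. Density at the 1 Mb scale does not account for it, since the share of gaps under 1000 bp was 3.26 times that of placements that keep the number of regions per bin. Splitting of single open stretches into pieces less than 150 bp apart may add to the short gaps but is not the whole cause, since gaps of 150 to 300 bp were 5.01 times as frequent as in those placements. After such regions were merged, the ratio of gaps under 1000 bp to placement over the chromosome was 3.41. The placements of the merged list kept at least 150 bp between regions, so 3.41 and the 3.64 of the full list rest on unlike placements. Gaps of 500 to 1000 bp were 1.86 times as frequent as in the placements within bins, but how far apart pieces can lie is not known. Wider splits, and accessible elements that gather around genes, both stay open, and the latter was not tested for want of an annotation of this build. Both sets of placements treated all sequence as able to hold a region. Stretches within a bin that cannot be aligned uniquely would also crowd the regions together, which was not tested either.

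The emptiest bin, on chromosome 12 from 16000001 to 17000000, held 4 regions with a mean peak value of 17.5, and the sparse bins at 2000001 to 4000000 on chromosome 4 had means of 15.2 and 14.7. Sequence that cannot be aligned uniquely and closed chromatin would both leave such bins empty, and no value here separates them.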
